A study of Mus musculus with 6 samples.

How the data were processed

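Liver RNA of 6 mice, 3 with floxed RECS1 (control) and 3 lacking RECS1 in hepatocytes (HKO), was measured on Affymetrix expression arrays. Per the labels' protocols, the livers were put in an RNA preservative, total RNA was extracted with Trizol, and biotinylated cRNA was made from 400 ng. Mice were 8 weeks old when the diet began. The deposited table holds log2 values of 38208 probe sets on 6 arrays, made by the authors with RMA, per the submitters' processing notes, which also name limma. Their versions, the background and summary settings and the probe annotation used are not given in the sources used here. The log2 scale was checked from the values, which lie between 0.498 and 13.64. RMA normalizes the arrays to a common distribution, so a shift of all transcripts between genotypes would not be seen, and it brings dim probe sets toward a common floor, which shrinks their fold changes.

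Probe sets were named through the platform annotation. Of the 38208, 13 are Affymetrix controls and were left out, 34325 have 1 gene symbol, 62 have several and 3808 are unnamed here. Of the single-gene probe sets 34131 matched a mouse gene by identifier in the reference gene table (assembly GRCm38.p6, used for names and gene order only), which changed 0 symbols. Each of the 18029 genes was represented by its probe set with the highest mean over all 6 arrays. Where probe sets of a gene disagree, this choice sets the value. Of the 182 genes past the threshold, 39 have another probe set above the median brightness. In 37 of these all such probe sets had the same sign, and in 31 another probe set showed at least 50 percent of the change.

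Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, HKO minus control, with genotype as the only term), with Benjamini-Hochberg adjustment over all 18029 genes and a threshold of 0.05. Values are log2 fold changes with their standard errors, the median standard error being 0.093. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so single genes were tested only in the model across all genes. Gene lists (38, each with at least 5 measured members) were tested with camera, with a preset inter-gene correlation of 0.01, and with fry, adjusted over the lists. The lists cover the TMBIM family, TLR4 signalling, NF-kB inflammatory targets, the acute phase and interferon responses, fatty acid, triglyceride and cholesterol synthesis, fatty acid oxidation, lipid storage, lipoproteins, bile acids, gluconeogenesis, glycolysis, insulin signalling, the unfolded protein and integrated stress responses, lysosome, ESCRT machinery, autophagy, apoptosis, fibrosis, oxidative phosphorylation, xenobiotic metabolism, NRF2 targets, cell cycle, circadian clock, immediate early genes, sex-biased liver genes, and markers of hepatocytes, macrophages, neutrophils, lymphocytes, endothelial cells, stellate cells, cholangiocytes, erythrocytes, and adipocytes with pancreas.

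The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took Tmbim1 and its family, then in each direction the 15 genes with the largest fold change among those with an adjusted p under 0.05, a mean above the median gene (4.69) and no overlap between the groups, and for each list the 4 members with the lowest p. It left 5 genes with provisional symbols unnamed. The alternatives were quantile normalization, centring on array medians, leaving out the dimmer part of the genes, the median of the probe sets of a gene, testing each probe set on its own, eBayes with trend and robust options, array weights, the replicate number as a block, other thresholds, an estimated inter-gene correlation, and leaving out each array in turn. A version of the NF-kB list without Nfkbia and the choice of each gene's probe set by its mean over the control arrays alone were added after the data were seen. Number 1, 2 or 3 of a sample is not stated to be shared between genotypes, so no block was used in the comparison itself.

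The steps were tested on simulated data for 18029 genes, with 200 genes changed and the 26 measured lysosome genes raised by 0.5 log2 units. Genes were drawn independently, with the spread of limma's own fit, so the false share holds for that model and not for genes that vary together. Of the 200 genes, those changed by 0.5, 1 and 2 log2 units passed in 38.8%, 94% and 97%, and 4 of all 168 calls (2.4%) were false. A difference of 0.5 log2 units in a single gene was therefore missed more often than found. The 6 arrays held no pair with identical values.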

Results

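Gene expression was measured in livers of mice with floxed alleles of RECS1 (control, n = 3) and of mice lacking RECS1 in hepatocytes (HKO, n = 3). RECS1 is an older name of Tmbim1, a membrane protein of the TMBIM family. All animals were C57BL/6, were fed a high-fat diet for 8 weeks and were 16 weeks old. Each array was hybridised with RNA of 1 liver sample, and the labels describe the 3 samples of a genotype as biological samples. The deposited log2 intensities had medians between 3.923 and 3.953 over the 6 arrays. Correlations across the 18029 genes lay between 0.9948 and 0.9964 within a genotype and between 0.991 and 0.994 across genotypes. The first principal component held 45.1% of the variance, with control arrays between -16.59 and -13.87 and HKO arrays between 9.73 and 20.31. The number of arrays limits the precision of every value below.

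The targeted gene was examined first. Tmbim1 fell in HKO liver from 7.65 ± 0.08 to 7.13 ± 0.07 (log2, mean ± SD, n = 3 each), a log2 fold change of -0.52 ± 0.08 (SE) or 0.697 times the control level (limma, Benjamini-Hochberg adjusted p = 0.026). All 3 HKO values lay below all 3 control values. Of the other 6 family members, none passed the test. Grina stood at 0.16 (log2 fold change, adjusted p = 0.586), Ghitm at 0.08 (0.707), Tmbim6 at 0.07 (0.758) and Tmbim4 at 0.05 (0.862), values that leaving out 1 array moved to between -0.027 and 0.245, and the family list was not shifted (camera adjusted p = 0.967). Without any 1 of the 6 arrays the Tmbim1 adjusted p lay between 0.065 and 0.0967, with fold changes from -0.554 to -0.475, and with the replicate number as a block it was 0.0828. Tmbim1 has 1 probe set, and whether it lies inside the deleted part of the gene is not given in the sources used here, so its fall is a limited check of the labels.

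The comparison of the genotypes asks which liver transcripts differ when hepatocytes lack Tmbim1 under a high-fat diet. Of 18029 genes, 101 rose and 81 fell in HKO liver (limma, adjusted p under 0.05). The largest rise among the genes named by the preset rule was that of Cyp2b9, a cytochrome P450 that female mouse liver expresses more than male liver, from 3.46 ± 0.25 to 9.75 ± 0.38 (log2 fold change 6.28 ± 0.20, adjusted p = 4.48e-06). Ctsk, a cysteine protease best known from osteoclasts, rose by 3.63 ± 0.15 (1.17e-05). Other risen genes were Gadd45g, a stress-inducible growth regulator, at 2.07 ± 0.22 (0.00412), Hamp2, a hepcidin, at 1.92 ± 0.34 (0.049), and Rad51b, a recombination factor, at 2.09 ± 0.35 (0.0398). Hamp2 and Rad51b no longer passed in 5 of the 6 fits without 1 array each, and in 4 and 1 of 9 other refits. Each has another, dimmer probe set, at -0.026 and 0.225. The control levels of Cyp2b9, Ctsk and Rad51b lie below the median gene (4.69), so their fold changes start from dim values.

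The largest fall among the named genes was that of Moxd1, a copper monooxygenase-like protein, from 7.95 ± 1.08 to 2.83 ± 0.10 (log2 fold change -5.11 ± 0.44, adjusted p = 0.00171). Serpina4-ps1 (-3.26), the ferritin receptor Scara5 (-3.03), the trefoil peptide Tff3 (-2.72), the transcription factor Zbtb16 (-2.17) and Enho, which encodes the liver peptide adropin (-1.94), also fell. So did C8b (-1.77) and C6 (-1.74), which encode terminal complement components, Serpina12, the adipokine vaspin (-1.65), Cav1, the coat protein of caveolae (-1.19), the vasopressin receptor Avpr1a (-1.14), Phlda1 (-1.14) and Fam47e (-1.20). In the 6 fits without 1 array, Serpina4-ps1, Zbtb16 and Fam47e no longer passed in 4, Cav1 and Avpr1a in 3 and Scara5 in 1. The HKO level of Moxd1 lies below the median gene. Pag1 had a value of -1.76 by its brightest probe set, while its other 3 probe sets stood at 0.31, 0.15 and 0.10, and Scara5 has another, dimmer probe set at 0.00.

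Of the 182 genes past the threshold, 82 differed by at least 2-fold (58 higher, 24 lower). At an unadjusted p under 0.01 there were 839 genes (386 higher, 453 lower), against 180.3 expected by chance. Fewer genes passed without control 1 (94), control 2 (81), control 3 (84), HKO 1 (78), HKO 2 (161) or HKO 3 (92). In all 6 such fits 57 genes (39 higher, 18 lower) passed.

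**Figure D1:**
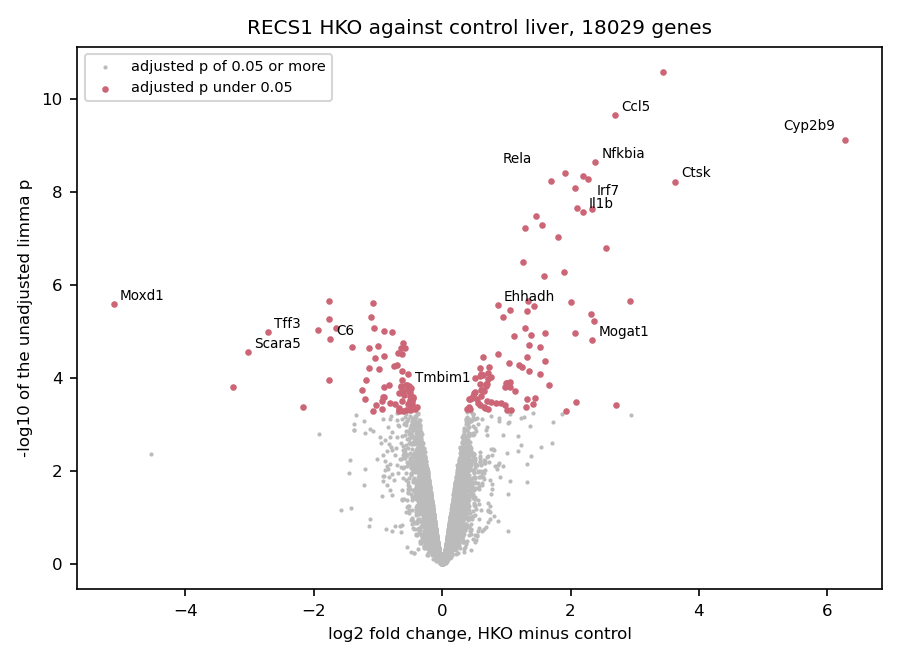
Each point is 1 of 18029 genes, with the log2 fold change (HKO minus control, n = 3 each) on the horizontal axis and minus log10 of the unadjusted limma p on the vertical axis; red points have an adjusted p under 0.05. The points with the lowest p lie on the right, with Cyp2b9 farthest out at 6.28, and Moxd1 lies farthest to the left at -5.11.

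Inflammatory genes stood out among the risen genes. Of 22 measured NF-kB inflammatory targets, 10 rose, by 1.32 to 2.69 log2 units, and 12 did not pass, with values between -0.30 and 0.29. The chemokine Ccl5 rose from 5.16 ± 0.06 to 7.85 ± 0.04 (log2 fold change 2.69 ± 0.07, adjusted p = 1.94e-06), the cytokine Il1b by 2.19 ± 0.11 (3.69e-05), the prostaglandin synthase Ptgs2 by 1.55 ± 0.08 (6.17e-05) and the chemokine Cxcl10 by 2.55 ± 0.16 (0.000159). Ptgs2 went from 1.28 to 2.84, below the median gene in both genotypes, so its difference is one of dim values, and its other probe set stood at 0.08 (0.776). The same 10 passed adjusted over the list alone and in all 6 fits without 1 array. The list was shifted up (camera adjusted p = 3.82e-16; adjusted p = 0.172 with an estimated correlation; fry 0.00324).

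Of 18 measured members of the TLR4 pathway, 2 rose, over all genes and adjusted over the list alone. Rela, the NF-kB subunit p65, rose by 1.91 ± 0.07 and the adaptor Myd88 by 1.70 ± 0.07 (both 1.17e-05), while Irf3 stood at -0.24 (0.203) and Tirap at -0.31 (0.262). The TLR4 list had a median of -0.01, a mean of 0.17 and no camera shift (adjusted p = 0.289), with a fry adjusted p of 0.00423. The interleukin receptor Il1r1 rose by 2.07 ± 0.09 (1.45e-05), and its other probe set, with a control mean of 0.98, stood at 0.00. Of 23 measured apoptosis genes, the initiator caspase Casp8 rose by 1.29 ± 0.07 (6.71e-05) and 22 did not pass, with the same count adjusted over the list alone (list adjusted p = 0.967).

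Nfkbia, the NF-kB inhibitor and a feedback target of the pathway, rose by 2.38 ± 0.09 (9.98e-06) in its brightest probe set. Its other 4 probe sets stood at 0.12, 0.11, 0.08 and -0.02, and by the median of its 5 probe sets the gene stood at 0.11 (adjusted p = 0.627). The probe set was chosen by its mean over all 6 arrays, which the HKO values themselves raise.

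The interferon list did not move as a group. Irf7, a regulator of type I interferon genes, rose by 2.27 ± 0.09 (1.17e-05). Bst2, an interferon-induced membrane protein, fell by 0.42 (0.0481). Bst2 did not pass in any of the 6 fits without 1 array, nor in 3 of 9 other refits. The other 15 of 17 measured members did not pass. Among them, the log2 fold change of Ifit2 was 0.30, and 0.117 without control 2. That of Rsad2 was 0.33, and 0.078 without HKO 2. The counts were the same adjusted over the list alone (list adjusted p = 0.861; 0.0326, downward, without HKO 2). No acute phase gene of 20 passed over all genes and 3 fell adjusted over the list alone, with Orm1 at -0.51 (0.0984), Itih3 at -0.43 (0.163) and Saa1 at -1.45 (0.222; -0.945 without control 1). That list had a median of -0.32 and was shifted down (camera adjusted p = 6.03e-05; adjusted p = 0.418 with an estimated correlation; fry 0.15).

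Markers of immune cells were measured beside these genes. Of 25 macrophage and Kupffer cell markers none passed, and 1 fell adjusted over the list alone, with Cd163 at -0.48 (0.05; past the threshold in 7 of 9 other refits of all arrays and in none of the 6 without 1 array), Ccr2 at -0.36 (0.188) and a list median of 0.01 (adjusted p = 0.902; 0.0324, upward, without control 1). Of 13 neutrophil markers none passed by either adjustment, with S100a8 at -0.79 ± 0.55 and S100a9 at -0.66 ± 0.42 (-0.10 and -0.11 without control 1; list 0.707). Among 22 lymphocyte markers Ccl5 alone passed, by either adjustment, with Cd4 at -0.20 and Cd2 at -0.26 (-0.104 and -0.099 without control 1; list 0.902; 0.0208 without control 1).

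**Figure D2:**
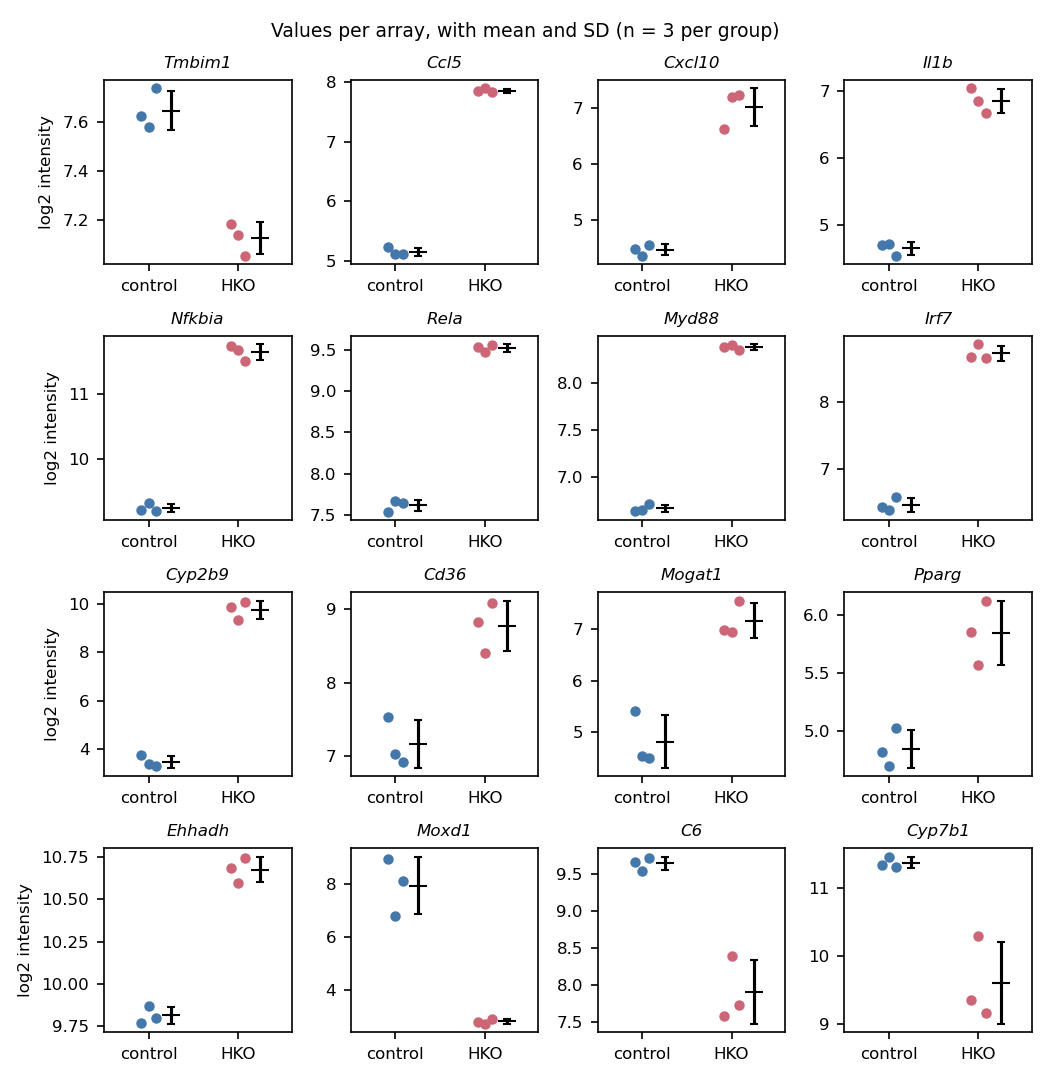
Dots are log2 intensities of single arrays for 16 genes, control in blue and HKO in red, with the mean and SD (n = 3) beside them; each panel has its own vertical axis. The Ccl5 values sit near 5.16 in control and 7.85 in HKO liver, and Tmbim1 near 7.65 and 7.13.

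**Figure D3:**
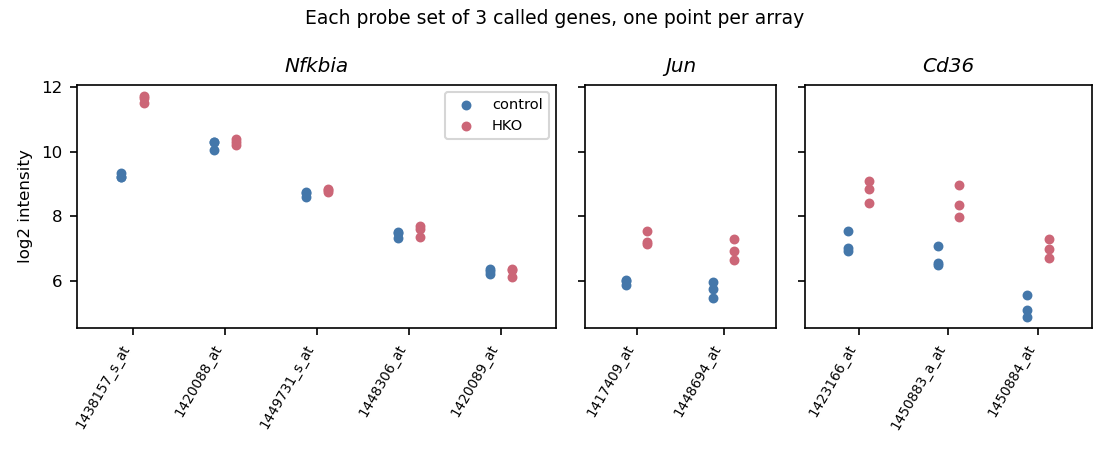
Log2 intensities of each probe set of Nfkbia, Jun and Cd36 on the 6 arrays, control in blue and HKO in red. For Nfkbia the groups part in 1 of 5 probe sets (2.38), and for Jun (1.33 and 1.22) and Cd36 (1.61, 1.72 and 1.81) they part in every probe set.

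Of 25 measured genes of fatty acid oxidation and targets of peroxisome proliferator-activated receptor alpha (PPARa), 5 rose over all genes and 11 adjusted over the list alone, and none fell. The peroxisomal enzyme Ehhadh rose by 0.87 ± 0.08 (adjusted p = 0.00172), the acyl-CoA thioesterases Acot3 by 2.36 ± 0.23 (0.00287) and Acot4 by 0.87 ± 0.10 (0.00878), and the pantetheinase Vnn1 by 0.72 ± 0.10 (0.0215). Vnn1 no longer passed in 5 and Acot4 in 2 of the 6 fits without 1 array. The list median was 0.27 (camera adjusted p = 3.88e-14; adjusted p = 0.135 with an estimated correlation; fry 0.00423).

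Of 25 lipid storage genes and PPARg targets, 5 rose over all genes and 11 adjusted over the list alone, and none fell. Mogat1, a monoacylglycerol acyltransferase, rose by 2.34 ± 0.26 (0.00554), the fatty acid transporter Cd36 by 1.61 ± 0.20 (0.0113), the receptor Vldlr by 0.94 ± 0.09 (0.00256) and Pparg itself by 1.00 ± 0.15 (0.0246). Pparg no longer passed in 5 and Cd36 in 3 of the 6 fits without 1 array. The lipid droplet gene Cidea had a larger difference, 2.95 ± 0.54, that did not pass (0.0549) but did in 4 of 9 other refits of all arrays and without HKO 2 (0.042). The list was shifted up (1.7e-07; adjusted p = 0.26 with an estimated correlation; fry 0.0316).

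Lipid synthesis showed no single gene past the threshold. None of 25 fatty acid and triglyceride synthesis genes passed by either adjustment, with Srebf1 at 0.34 (0.246), Fads1 at 0.41 (0.248) and Mlxipl at -0.35 (0.118). Their list was shifted up (0.00917; adjusted p = 0.857 with an estimated correlation; fry 0.675), but not without control 1 (0.158), HKO 1 (0.0667) or HKO 3 (0.722). None of 20 cholesterol synthesis genes passed by either adjustment, with Sqle at -0.74 ± 0.47 (past the threshold without HKO 3, at -1.37) (list 0.157; 9.89e-14 without HKO 3 and 0.0168 without control 1, both downward). Of 20 lipoprotein genes, Apom, an apolipoprotein of high-density lipoprotein, fell by 0.76 ± 0.10 (0.0139) by either adjustment, though not in 2 of the 6 fits without 1 array, with Scarb1 at -0.48 (0.199) (list 0.967).

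Sex-biased liver genes were tested as a pair of lists. Of 13 measured female-biased genes 5 rose over all genes and 7 adjusted over the list alone, with a list median of 1.01. Beside Cyp2b9 and Acot3 these included Hao2, a hydroxyacid oxidase, at 2.93 ± 0.25 (adjusted p = 0.00163) and the transporter Slc22a27 at 2.31 ± 0.21 (0.00229). Of 11 measured male-biased genes 2 fell over all genes and 8 adjusted over the list alone, with a median of -0.89. Cyp7b1, an oxysterol hydroxylase, fell from 11.37 ± 0.08 to 9.61 ± 0.60 (-1.76 ± 0.25, 0.022) and C6 fell by 1.74 ± 0.19 (0.00544), while Slco1a1 stood at -1.91 ± 0.41 (0.0908). Cyp7b1 no longer passed in 5 of the 6 fits without 1 array, and the control levels of Hao2 and Slc22a27 lie below the median gene. The female-biased list was shifted up (3.77e-11; adjusted p = 0.235 with an estimated correlation; fry 0.0105) and the male-biased list down (1.09e-09; adjusted p = 0.379 with an estimated correlation; fry 0.0973).

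Of 23 genes of xenobiotic metabolism 3 rose over all genes, and 9 rose and 2 fell adjusted over the list alone. The 3 were Cyp2b9, Cyp2b13 and Cyp2c38, and Cyp2b9 and Cyp2b13 are also among the female-biased genes above. The cytochromes Cyp2b13 and Cyp2c38 rose by 1.38 ± 0.15 (0.00445) and 1.53 ± 0.18 (0.00705), and the nuclear receptor Nr1i3 (CAR) stood at 0.52 (0.0616). This list was shifted up (2.41e-05; adjusted p = 0.135 with an estimated correlation; fry 0.00324). Of 23 NRF2 targets 3 rose by either adjustment: the glutathione transferases Gstm2 by 1.13 ± 0.17 (0.0289) and Gsta2 by 1.45 ± 0.24 (0.036), and the quinone reductase Nqo1 by 1.01 ± 0.18 (0.0481). The NRF2 list was shifted up (4.91e-08; adjusted p = 0.392 with an estimated correlation; fry 0.117). Among 22 genes of bile acid synthesis and transport, Slco1a4 (1.66, 0.0257), the reductase Akr1d1 (0.72, 0.0178) and the exporter Abcc3 (0.65, 0.0457) rose and Cyp7b1 fell, and 4 rose and 6 fell adjusted over the list alone (list 0.967). In the 6 fits without 1 array, Gsta2, Nqo1, Slco1a4 and Abcc3 no longer passed in 5 and Gstm2 and Akr1d1 in 4.

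In glucose metabolism, 2 of 19 gluconeogenesis and glycogen genes rose over all genes and 6 adjusted over the list alone. Igfbp1, an insulin-repressed binding protein, rose by 1.04 ± 0.13 (adjusted p = 0.0123) and Ppp1r3g, a glycogen-targeting phosphatase subunit, by 2.70 ± 0.47 (0.0436), while G6pc stood at 0.36 (0.135). Igfbp1 no longer passed in 1 and Ppp1r3g in 4 of the 6 fits without 1 array. The list was shifted up (0.000146; adjusted p = 0.336 with an estimated correlation; fry 0.091). No glycolysis gene of 12 passed by either adjustment, with Gckr at 0.27 (list 0.546). Of 23 insulin signalling genes Igfbp1 alone passed over all genes, and 1 rose and 3 fell adjusted over the list alone, with Irs2 at -0.33 (list 0.707). None of 31 oxidative phosphorylation genes passed by either adjustment, yet 28 had positive values, with a median of 0.08 (0.00101; adjusted p = 0.525 with an estimated correlation; fry 0.117).

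Of 24 unfolded protein response genes, the chaperone Dnajb9 rose by 0.55 ± 0.09 (0.0374), and adjusted over the list alone 1 rose and 4 fell. Sdf2l1 stood at -0.79 (0.142) and Hyou1 at -0.44 (0.176), with a list median of -0.18 (0.00101, downward; adjusted p = 0.542 with an estimated correlation; fry 0.303). Of 21 integrated stress response genes Vldlr alone passed, by either adjustment, with Ddit4 at 0.86 ± 0.24 (0.191) (list 0.00639, upward; adjusted p = 0.418 with an estimated correlation; fry 0.117). Among 22 immediate early and heat shock genes, the AP-1 subunit Jun (1.33 ± 0.11, 0.00163) and the nuclear receptor Nr4a1 (1.01 ± 0.15, 0.0249) rose and the small heat shock protein Hspb1 fell by 0.61 (0.0289). Without 1 array, Dnajb9 and Nr4a1 no longer passed in 5 and Hspb1 in all 6 of the fits. Adjusted over the list alone 5 rose and 4 fell (list 0.986). None of 27 cell cycle genes passed over all genes and 2 rose adjusted over the list alone, with Mcm3 at 0.41 (0.105) and Mcm2 at 0.43 (0.126) (list 0.0015, upward; adjusted p = 0.524 with an estimated correlation; fry 0.303). None of 19 circadian clock genes passed over all genes, and 2 rose and 1 fell adjusted over the list alone, with Cry2 at 0.33 (0.0805) and Nr1d1 at -0.53 (0.132) (list 0.181).

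Organelle lists stayed near 0. None of 26 lysosome genes (median 0.01, list adjusted p = 0.707), 28 genes of the ESCRT machinery and multivesicular bodies (0.00, 0.967) and 23 autophagy genes (-0.05, 0.707) passed by either adjustment. Hexa had a log2 fold change of 0.38 ± 0.15, which was 0.208 without HKO 3. Rab5a stood at 0.24 ± 0.08 and Atg7 at 0.22 ± 0.07.

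Markers of other liver cells did not pass either. None of 18 hepatocyte markers (list adjusted p = 0.841), 20 endothelial markers (0.986), 17 stellate cell and fibroblast markers (0.937), 8 erythrocyte markers (0.967) or 27 fibrosis and matrix genes (0.967; 0.0392, downward, without HKO 3) passed by either adjustment, with Col1a1 at 0.18 ± 0.10. None of 13 cholangiocyte markers passed, with Sox9 at -0.66 ± 0.18 (list 0.145; 0.048, downward, without control 1). Of 15 adipocyte and pancreas markers none passed over all genes and 1, Cidea, rose adjusted over the list alone (list 0.546). The actin 3' to 5' difference, a sign of RNA integrity, was 1.14 ± 0.08 in control and 1.13 ± 0.07 in HKO liver.

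By camera with its preset correlation 14 of 38 lists were shifted, 11 up and 3 down. With an estimated correlation the count was 0, and by fry, which tests the average movement of the genes of a list, 6. A few strongly changed genes can carry a fry pass. The TLR4 list passed (fry adjusted p = 0.00423) with 2 of 18 genes past the threshold and a median of -0.01. In the other 9 ways to part the arrays into 3 and 3, camera with its preset correlation gave 5 to 17 lists and fry 0. Each of these 9 mixes the genotypes in both groups and keeps part of their difference, so its lists are not a count of false shifts. Since no list passed with an estimated correlation, a camera shift by itself is not taken as evidence of a difference between the genotypes.

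**Figure D4:**
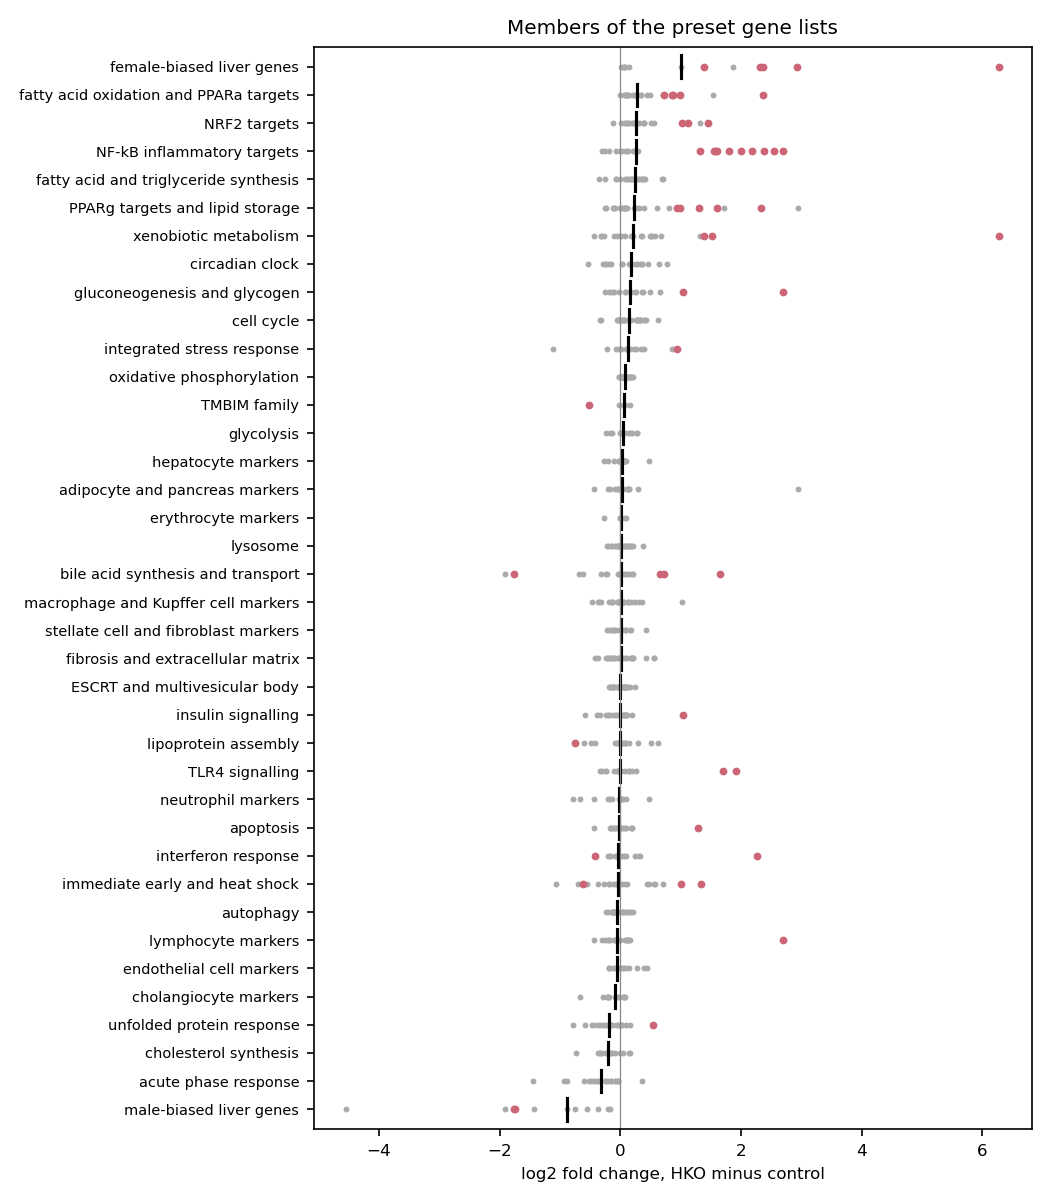
Each dot is the log2 fold change (HKO minus control) of a measured member of a preset list, red where its adjusted p over all genes is under 0.05, and the black bar is the list median. The female-biased list has the highest median (1.01) and the male-biased list the lowest (-0.89), and 10 of 22 NF-kB targets stand apart from the other 12.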

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

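The tests on inflammatory genes, sex-biased genes and the count of genes over other splits were chosen after the results were seen. The counts of lists and of genes at an unadjusted p under 0.01 over other splits were planned before.

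Among the 3870 probe sets with no gene symbol or several, which entered no comparison above, 21 differed between the genotypes (limma over all probe sets, adjusted p under 0.05), 10 higher and 11 lower in HKO liver. No explanation was tested for them.

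All of the 20 genes with the lowest p were higher in HKO liver, 8 of them from the NF-kB or TLR4 lists. Of these 20, 7 have further probe sets, and in 6 of the 7, all but Wdfy1, none of these showed at least 50 percent of the change. For Il1r1, Ptgs2, Il12b, Cxcl15 and Cxcl9 the other probe set lay below the median gene (4.69), between 0.98 and 3.49 in control liver. Fold changes of such dim probe sets are shrunk, so their values do not decide whether the whole gene rose. The probe sets used for Ptgs2, Il12b and Cxcl15 were dim in control liver too. Only for Nfkbia were the others above the median gene, from 6.30 to 10.21. The marker lists gave no sign of more immune cells in HKO livers. The highest median of the macrophage, neutrophil and lymphocyte lists, without NF-kB targets, was 0.01 (95% bootstrap intervals of the 3 medians end at 0.07 or below). A full interferon response after Irf7 is argued against by the other 16 interferon genes, with a median of -0.04 (-0.11 to 0.05). These intervals resample the genes of a list and not the mice, so they leave out the spread between mice. Without control 1 the macrophage and lymphocyte lists passed upward (camera adjusted p = 0.0324 and 0.0208), so a small rise of immune cells is not excluded. In that test the lymphocyte list still held Ccl5, itself 1 of the NF-kB targets that rose. For Nfkbia, a signal of the brightest probe set and not of the whole gene could account for the rise, since the other 4 probe sets reached at most 0.12. A shift added to single probe sets after RMA stays open. Of the 10 NF-kB targets that rose, 4 have HKO values that recur exactly at another probe set (6 of 30 values, where 3.1 are expected at that brightness and at most 1 came up in 10000 simulated shifts). The simulated shifts were an arbitrary amount for each gene. The counts go against such a shift of all 10, and against it for Tnf and Cxcl10, with 2 such values each. They do not bear on other kinds of shift. The rule set for this test asked for all 10 genes or none, so by that rule it cannot tell. Il6 and Ccl2 have 1 each, which a simulated shift can also give, so they and the other 6 stay undecided. Values exchanged between probe sets, a step before RMA and an effect of genotype were not tested and stay open too.

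Of 13 female-biased genes 5 rose, and of 11 male-biased genes 2 fell (fry adjusted p = 0.0105 and 0.0973). Mice of the other sex in the HKO group are argued against, since the largest absolute change among Eif2s3y, Kdm5d, Uty and Xist was 0.15, with Eif2s3y at 6.98 in control and 6.92 in HKO liver and Xist at 1.42 and 1.39. Dependence of the list means on 1 array is argued against. Without 1 array the mean of the female-biased list was 1.33 to 1.59, against 1.43 with all arrays, and that of the male-biased list -1.68 to -1.09, against -1.30. Single calls were lost with fewer arrays, as that of Cyp7b1 in 5 of the 6 fits without 1 array. Its fold change stayed between -2.103 and -1.543 there, against -1.761 with all arrays. An effect of genotype on the hormonal control of these genes may remain and was not tested.

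Other splits of the arrays gave fewer genes. Of the 10 ways to part 6 arrays into 3 and 3, 1, the real one, gave as many genes (182, against at most 0 in others by limma) and 1 as many at an unadjusted p under 0.01 (839, against at most 178). For lists tested by camera, 3 of the 10 gave as many as the 14 of the real split, with up to 17 in another, while fry gave 6 in the real split and 0 in the others. So few splits allow no share under 0.05. Every other split mixes the genotypes in both groups, which lowers a genotype difference and adds it to the spread within groups. For genes and lists that differ by genotype, low counts by limma and fry were therefore likely in these splits. The counts do not measure calls made by chance, and no conclusion is drawn from them.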

How the results depend on the processing

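The limits are the 6 arrays, for dim genes the signal over background, and the substrain and litters of the mice, which the labels do not give. The number past the threshold was 125 to 250 in the 8 planned refits of all arrays, against 182 genes. Of these refits, that with each probe set tested on its own counts probe sets and not genes. The number of genes was 142 with at least 1.5-fold, 344 at an adjusted p under 0.1 and 78 to 161 without 1 array. The count at an unadjusted p under 0.01 was 1394 with each probe set tested on its own, over more tests, against 839. Tmbim1 stayed at -0.52 with the replicate block but no longer passed (adjusted p = 0.0828, range 0.0094 to 0.0967 over all its alternatives), and without 1 array it lay between -0.554 and -0.475 and passed in none of the 6. The block left 125 genes, 104 of them shared with the 182; deviations of same-numbered arrays correlated at -0.09, 0.07 and 0.11, and 2 arrays correlated best with their own number. An estimated inter-gene correlation left 0 of 14 lists, with adjusted p of 0.172 for NF-kB targets, 0.135 for fatty acid oxidation and for xenobiotic metabolism, 0.26 for lipid storage, 0.235 and 0.379 for female-biased and male-biased genes, 0.392 for NRF2 targets, 0.418 for acute phase and integrated stress response, 0.336 for gluconeogenesis, 0.525 for oxidative phosphorylation, 0.542 for the unfolded protein response, 0.524 for cell cycle and 0.857 for fatty acid synthesis. With dim genes left out, the integrated stress response (0.0665) and cell cycle (0.12) lists no longer passed, with fewer genes tested. Without 1 array, fatty acid synthesis ranged from 1.16e-06 to 0.722, macrophage markers from 0.0324 to 0.929, interferon from 0.0326 to 0.929 and fibrosis from 0.0392 to 0.974, the lowest of the last 3 being passes opposite to the direction with all arrays. By the median of its probe sets Pag1 turned to 0.044. The cholesterol synthesis, autophagy and circadian clock lists, which did not pass with all arrays, passed in 1 refit of all arrays each. The cause was not tested for the other changes. The NF-kB list without Nfkbia, chosen after the data were seen, still passed by camera with its preset correlation (adjusted p = 5.56e-14). An estimated correlation was not tried for that version. With the probe set brightest in the control arrays, also chosen after the data were seen, 183 genes passed, 179 of them shared with the 182, and Nfkbia (0.08) and Ptgs2 (0.08) no longer did. Of 57 named genes that passed, 9 to 25 no longer did without 1 array, 12 with the block and 10 with the trend and robust options, and at most 2 in each other refit, beside Pag1, while 0 to 6 of 110 named genes gained a pass in each refit.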

Other observations

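The genes and the test of neighbours here were chosen after the values were seen. Several of the genes with the lowest p lie outside the preset lists and the rule for named genes. The chemokine Cxcl15 had the lowest p of all, with a log2 fold change of 3.43 (adjusted p = 4.54e-07) from a control level of 1.71 ± 0.03 to 5.15 ± 0.06, while its other probe set, brighter in control liver (3.17 ± 0.14), stood at -0.03 (0.948). The cytokine genes Il12b (2.34), Ifna4 (2.19), Ifnb1 (2.10) and Il12a (1.47) and the chemokine Cxcl9 (1.90) also rose. Il12b and Cxcl9 have another probe set each, dimmer in control liver, at 0.03 (0.951) and -0.01 (0.985). In control liver Cxcl15, Il12b, Ifna4, Ifnb1 and Il12a lay below the median gene of 4.69, so their fold changes start near the floor of the arrays. Slc16a7, a monocarboxylate transporter (1.28, 0.00388), and Rab30, a Golgi GTPase (1.06, 0.00204), rose as well. Unc13b, a vesicle priming protein (-1.07, 0.00169), Ces4a, a carboxylesterase (-1.11, 0.00256), and Dynll1, a dynein light chain (-1.06, 0.00388), fell. Wdfy1 (1.25, 0.000297), with other probe sets at 1.66, 0.92, 0.07 and -0.77, and Nnt (1.43, 0.00173), with another at 1.85, rose. In both Nnt probe sets all 3 HKO values lay above all 3 control values. Whether control and HKO mice were littermates of 1 C57BL/6 substrain is not given in the labels. A difference of substrain or litter can therefore not be told apart from an effect of the deletion. This limits what these values and the other differences between the genotypes show. Among the 100 tested genes nearest to Tmbim1 on its chromosome, 2 passed (Mogat1 and Ankzf1), or 2% against 1% of other genes (Fisher's exact test p = 0.26), and Wdfy1 lies 56 tested genes from Tmbim1, just outside that window. Nnt lies on chromosome 13 and Tmbim1 on chromosome 1, so the test of neighbours does not bear on Nnt.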
